A study of Mus musculus with 2 samples.

How the data were processed

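The deposited files held 2 Chromium single-cell 3' v3 libraries of cells sorted from mouse gingiva, 1 normoglycemic and 1 diabetic, each pooled from 4 mice with no replicates per the labels. The values are raw UMI counts per gene and cell that the authors made with Cell Ranger, for 32285 genes and 4 antibody capture features. The program version is 4.0.0 per the file headers and 6.0.2 per the submitters' processing notes, which also give the genome build mm10 and no annotation release. The normoglycemic matrix held 11280 barcodes with 89339733 UMIs (median 5161 per barcode) and the diabetic matrix 10496 barcodes with 78220582 UMIs (median 4542.5), whereas 10000 cells were loaded per lane per the labels. The lowest barcode had 500 UMIs in both matrices, so the deposited counts had been filtered. The antibody capture features were kept apart from the genes in every step.

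Cells were kept with at least 500 UMIs, at least 200 genes and at most 15% of UMIs from mitochondrially encoded genes, which removed 332 normoglycemic and 236 diabetic barcodes. Scrublet, which simulates doublets and scores each cell against them, marked 2 normoglycemic and 0 diabetic cells where 8.76% and 8.21% were expected from the cell numbers. It had therefore not worked here. The 2 cells were removed, and an alternative removed the highest doublet scores up to the expected rate (927 and 768 cells). In all, 10946 normoglycemic and 10260 diabetic cells were analysed, with medians of 5302 and 4631.5 UMIs and 1281 and 1105 genes.

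Counts were scaled to 10000 UMIs per cell and log-transformed, and both libraries were clustered together without batch correction, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 28 clusters. Sex-linked genes and antigen receptor segments were left out of the variable genes. Each cluster took the class whose markers scored highest. Clusters scored as alpha-beta T, regulatory T or NK cells were joined into 1 class, and so were type 1 and type 2 conventional dendritic cells. A name needed at least 3 markers detected in at least 20% of the cluster's cells, and a cluster stayed unnamed if its 10 leading genes held more markers of another class, or 3 or more cell cycle or histone genes. One cluster was kept out by a list of secretory epithelial genes written after the data were seen. Markers, 46 gene lists, 25 regulator genes, comparisons, thresholds and the first set of alternative settings had been fixed before the data were examined. Scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12, scikit-image 0.26.0, scikit-learn 1.9.0 and matplotlib 3.10.9 were run under Python 3.11.15, and edgeR 4.0.16 and DESeq2 1.42.0 under R 4.3.3.

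Shares of cells were given with exact Clopper-Pearson 95% intervals and their differences with Newcombe's interval. Genes were compared in the 8 classes with at least 100 cells in each library, from UMI counts summed over the class and scaled to counts per 1000000 UMIs of the class (CPM). Ratios were diabetic over normoglycemic with exact conditional binomial 95% intervals, and log2 ratios used a pseudocount of 0.5 counts. No test across replicates was possible, so no p-values were computed. Named genes needed at least 50 CPM in the library where they were higher, at least 50 counts, at least 0.5 times the level of the other cells of that library, and an interval wholly beyond 1.5-fold. A named gene could thus lie below the level of the other cells, and free RNA was then not excluded as its source. They were ranked by the interval bound nearer to 1, with up to 12 per direction and class (192 genes). The limit of 8 named genes per direction in myeloid and 5 in lymphoid classes, the choice of lists described and the 3 members named per list were set after the data were seen, to limit length. Mature dendritic cells were described by lists alone.

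For each list and class, members with at least 10 CPM in either library were taken, and at least 5 were needed. The median log2 ratio was given with an order-statistic 95% interval and compared with 10000 random lists matched in size and in expression over 20 bins. A member counted as higher or lower when its log2 ratio reached 1.5-fold, whatever its interval, and the members named were those with the highest CPM on the side of the median. The listed genes Il36g (present as Il1f9), Cxcl11, Clec7a and Mx1 were absent under those names from the feature table. Shares of cells with a UMI of a regulator gene were computed after thinning each cell to 1000 UMIs without replacement, cells below that depth left out. B cells served as a background, and a regulator was described where its share reached 3% in either library. Where a share was 0, the upper limit was 3 counts over the number of cells. Cells were called male with UMIs of Ddx3y, Eif2s3y, Kdm5d or Uty and none of Xist, and female with Xist and none of those.

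The alternative settings of this first set were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), a looser filter (200 genes only), doublets kept, Leiden resolutions 0.5 and 2.0, and each library clustered separately. For genes and lists they were trimmed mean of M values (TMM) scaling, DESeq2 size factors, every cell weighted equally and cells thinned to 1000 UMIs. For lists they were members without a CPM minimum or with at least 50 CPM, or without cell type markers, and for regulator shares thinning to 2000 UMIs or none. Added after the data were seen were removal of the highest doublet scores, removal of cells with over 100 tag counts, shares without non-immune cells, shares outside the CD11c gate, male-called or female-called cells alone, and resolution 2.0 for genes and lists. A setting needed at least 50 cells of a class in each library, except that female-called neutrophils were used below that number to weigh sex makeup. Also after the data were seen, list medians were computed within single clusters, and with each normoglycemic cluster weighted by its ratio of diabetic to normoglycemic cells, for neutrophils over the clusters of resolution 1.0 and for macrophages over those of resolution 2.0.

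The comparison was tested on simulated data with the class sizes of the real libraries, 1465 to 2948 genes per class and 200 changed genes. The intervals covered the true ratio for 94.34% to 96.2% of genes, and 0 of 18426 unchanged genes had an interval wholly beyond 1.5-fold. The comparison with other cells and the ranking of the named-gene rule were not simulated. Of genes changed to 2.0 times, 72.0% to 100.0% were recovered, of genes changed to 0.5 times 52.0% to 100.0%, and of genes changed to 4.0 or 0.25 times 100.0%. Planted lists of 20 genes at 1.5-fold reached percentile 100.0 of random lists in the classes simulated, and 17 of 800 unchanged lists fell in the outer percentiles below 1.0 or above 99.0. The simulation covered counting error only.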

Results

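Single-cell gene expression was measured in leukocytes sorted from mouse gingiva after bacterially induced inflammation, in 1 library from normoglycemic mice and 1 library from mice made diabetic with streptozotocin, a compound toxic to the insulin-producing beta cells of the pancreas. Each library pooled cells of 4 mice, taken after 2 weeks of inflammation and a further 2 weeks without it. The mice carried loxP sites around an exon of Foxo1 but no Cre recombinase to remove it, and their Foxo1 protein was normal per the series description. Sorting by flow cytometry discarded dead, endothelial and red blood cells, kept cells bearing CD45, the common leukocyte surface protein, and enriched cells bearing CD11c, an integrin of dendritic cells and many macrophages, by 20%. The normoglycemic library held 11280 barcodes with 89339733 unique molecular identifiers (UMIs) and the diabetic library 10496 barcodes with 78220582 UMIs, beside 10000 cells loaded per lane. After filtering, 10946 normoglycemic cells with a median of 5302 UMIs and 10260 diabetic cells with a median of 4631.5 UMIs remained. With 1 library per condition, no difference could be checked against replicates. Intervals of shares and gene ratios cover counting error only, and those of list medians the spread over the member genes. Each class name stands for cells that resembled that type by markers fixed before the data were examined (neutrophil-like cells, and so on). Both pools held cells with transcripts of Xist, which silences 1 X chromosome in females, and cells with Y-linked transcripts, called female and male below.

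The first comparison asked which cells the inflamed gingiva of diabetic and normoglycemic mice held, as part of the study's question of how diabetes alters the host response in periodontitis. Lymphoid cells made up a smaller share of the diabetic library. Together, alpha-beta T or natural killer (NK) cells, gamma-delta or type 17 T cells, type 2 innate lymphoid cells and B cells were 13.7% of normoglycemic cells (95% interval 13.04 to 14.33) and 6.93% of diabetic cells (6.45 to 7.44), a difference of -6.75 percentage points (-7.56 to -5.93). Alpha-beta T or NK cells were 6.51% (6.06 to 6.99) against 3.10% (2.77 to 3.45). Gamma-delta or type 17 T cells were 3.11% (2.79 to 3.45) against 1.85% (1.60 to 2.13) and B cells 2.92% (2.62 to 3.26) against 1.60% (1.37 to 1.86). Type 2 innate lymphoid cells were 1.13% (0.943 to 1.35) against 0.380% (0.270 to 0.519). Neutrophils were the most abundant class in both libraries, at 48.2% (47.2 to 49.1) of normoglycemic and 47.1% (46.2 to 48.1) of diabetic cells, and the difference of -1.07 points (-2.42 to 0.28) was within counting error. It turned to 9.32 points when the libraries were clustered separately and to -6.23 points without the highest doublet scores. With the looser cell filter, doublets kept or finer clusters, the gamma-delta or type 17 difference of -1.25 points shrank to between -0.452 and -0.394. Among the classes that the CD11c gate does not select, neutrophils were 77.4% (76.4 to 78.4) against 86.7% (85.8 to 87.6).

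The enrichment at the sort set part of the shares of those myeloid classes that the CD11c gate can select. Monocytes were 11.3% (10.7 to 11.9) of normoglycemic and 12.2% (11.5 to 12.8) of diabetic cells, macrophages 9.81% (9.26 to 10.4) against 9.93% (9.36 to 10.53), and conventional dendritic cells 9.03% (8.496 to 9.578) against 8.19% (7.66 to 8.73), a difference of -0.839 points (-1.6 to -0.0768). Mature dendritic cells, which migrate to lymph nodes, were 1.74% (1.499 to 1.998) against 1.39% (1.18 to 1.64), but their difference of -0.342 points reversed under 6 of the alternatives tried. Mast cells were 0.375% (0.269 to 0.508) against 0.273% (0.181 to 0.394). The macrophage difference of 0.12 points turned to -2.52 with finer clusters. Clustered separately, the libraries differed by 5.05 points in monocytes and -2.77 points in macrophages. Cells that are not leukocytes entered the diabetic library more often, at 8.85% (8.31 to 9.42) against 0.548% (0.419 to 0.705). They comprised fibroblasts at 2.74% against 0.210%, mural or muscle cells at 2.70% against 0.0548% and Schwann cells or melanocytes at 0.663% against 0.0640%. Epithelial cells with keratin genes were 1.41% against 0.110%, and salivary genes were found in the diabetic ones alone (Bpifa2 at 20430 CPM against 0). Secretory epithelial cells, kept out of the named classes by a gene list set after the data were seen, were 1.34% (1.12 to 1.58) against 0.110% (0.0567 to 0.191). Cells without a name, that secretory cluster included, were 6.49% (6.02 to 6.99) of the diabetic and 5.46% (5.05 to 5.91) of the normoglycemic library.

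**Figure D1:**
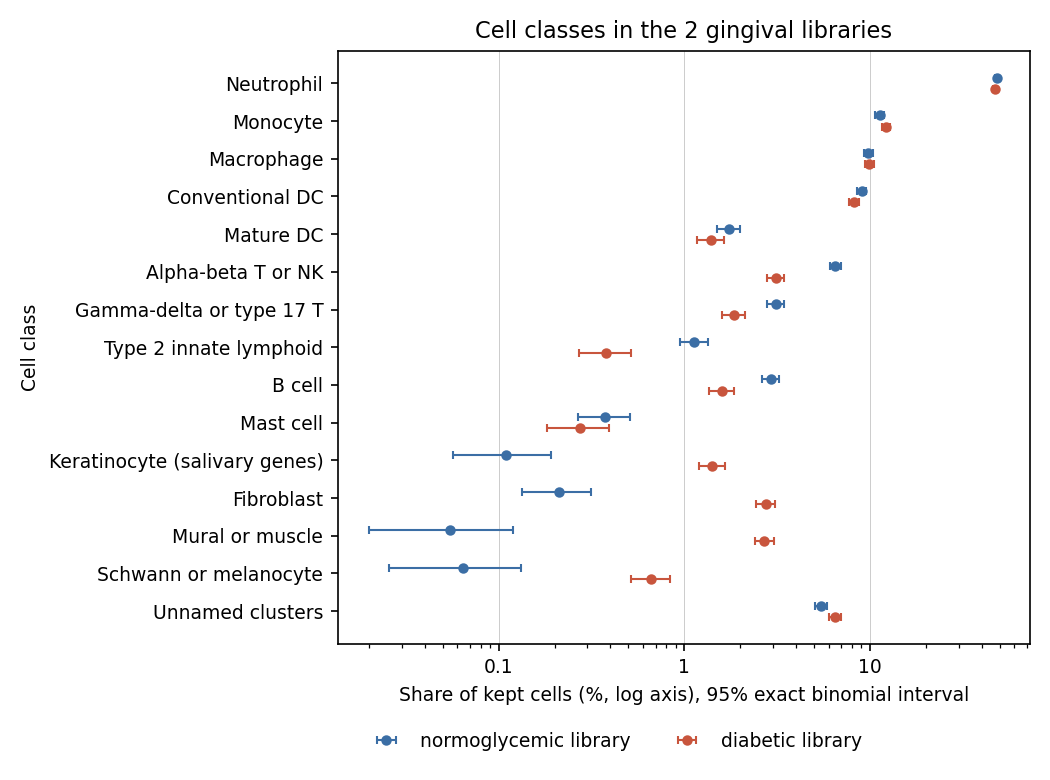
Share of kept cells in each class, in percent on a log axis, for the normoglycemic and diabetic libraries (1 library each), with exact 95% binomial intervals that cover counting error only. The lymphoid classes lay lower in the diabetic library (alpha-beta T or NK cells 3.10% against 6.51%) and the fibroblast and mural classes higher.

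Composition was also compared within the lymphoid and the antigen-presenting compartments. Among lymphoid cells, alpha-beta T or NK cells were 47.6% (45.1 to 50.2) of the normoglycemic and 44.7% (41.0 to 48.5) of the diabetic library, and B cells 21.4% (19.3 to 23.5) against 23.1% (20.0 to 26.3), both within counting error. Gamma-delta or type 17 T cells were 22.7% (20.6 to 24.9) against 26.7% (23.5 to 30.1) of lymphoid cells and type 2 innate lymphoid cells 8.28% (6.94 to 9.80) against 5.49% (3.93 to 7.42). Among macrophages, monocytes and dendritic cells, monocytes were 35.4% (33.9 to 37.1) against 38.4% (36.7 to 40.1) and macrophages 30.8% (29.3 to 32.4) against 31.4% (29.8 to 33.0). Conventional dendritic cells were 28.3% (26.8 to 29.9) against 25.9% (24.4 to 27.4) and mature dendritic cells 5.45% (4.72 to 6.25) against 4.4% (3.72 to 5.16). The monocyte difference changed sign with the stricter cell filter and the conventional dendritic cell difference with finer clusters. The macrophage difference did so with the looser filter, finer clusters and separate clustering, and the mature dendritic cell difference under 6 alternatives. Clustered separately, the difference was 12.1 points for monocytes, -10.2 for macrophages, -8.20 for type 2 innate lymphoid and 3.64 for alpha-beta T or NK cells. The gamma-delta or type 17 difference lay between 9.31 and 9.68 points with the looser filter, doublets kept or finer clusters.

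Cells called male and female did not spread evenly over the classes. A call needs a UMI of Xist or of a Y-linked gene. In the normoglycemic library 2519 of 5274 neutrophils had neither, against 190 of 1074 macrophages. Differences between classes may therefore follow detection as well as the sex of the mice, which was not tested. Among neutrophils with a call, 1.36% (0.956 to 1.86) of normoglycemic and 10.3% (9.02 to 11.7) of diabetic cells were called female, and among monocytes 6.75% (5.2 to 8.58) against 33.5% (30.4 to 36.7). Macrophages called female were 38.3% (34.9 to 41.8) against 47.1% (43.5 to 50.8) and conventional dendritic cells 47.2% (43.7 to 50.7) against 30.9% (27.4 to 34.7). In the lymphoid classes, female calls made up 33.3% (29.0 to 37.8) against 59.3% (52.4 to 66.0) of alpha-beta T or NK cells, 51.5% (45.3 to 57.7) against 64.1% (55.1 to 72.3) of gamma-delta or type 17 T cells, and 57.3% (50.6 to 63.8) against 47.2% (37.4 to 57.1) of B cells.

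**Figure D2:**
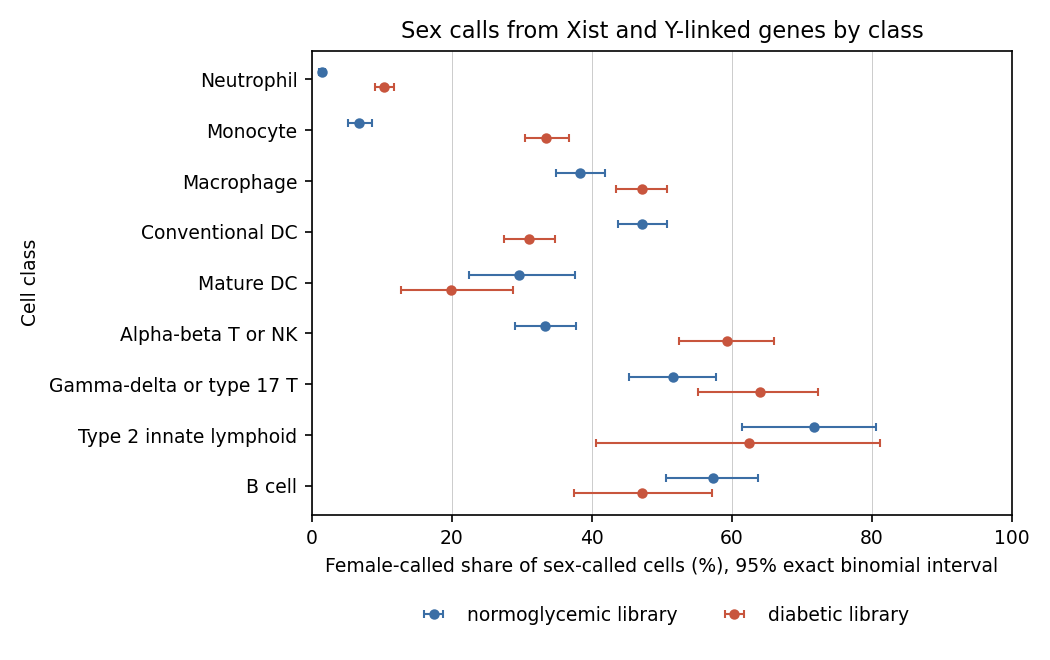
Percent of cells with a sex call that were called female, by cell class and library (1 library per condition), with exact 95% binomial intervals that cover counting error only. Neutrophils called female made up 1.36% of calls in the normoglycemic and 10.3% in the diabetic library.

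Macrophages were compared next, to describe how tissue phagocytes differed between the conditions, in 1074 normoglycemic and 1019 diabetic cells held mainly by cluster 1 in both libraries. Genes for presenting antigen on MHC class II molecules were lower in diabetic macrophages. Of the 10 measured members of this list, 8 were at least 1.5-fold lower and 0 were at least 1.5-fold higher. Cd74, the invariant chain that escorts class II molecules, stood at 10290 counts per 1000000 UMIs of the class (CPM) in normoglycemic and 3840 CPM in diabetic macrophages, a ratio of 0.373 (0.369 to 0.378). H2-Aa, a class II alpha chain, stood at 4937 and 1635 CPM (ratio 0.331, 0.326 to 0.337), and H2-Ab1, its beta chain partner, at 3818 and 1141 CPM (ratio 0.299, 0.293 to 0.305). H2-Eb1 was at 0.279 times its normoglycemic level (0.251 to 0.310). Finer clusters split the class unevenly between the libraries and left some macrophage-like cells unnamed, and Cd74 then stood at 0.729 and the list at -0.46, or at -0.78 with the unnamed macrophage-like groups included. With the normoglycemic finer clusters weighted to the diabetic mix of cells, the list stood at -0.88, with 7 of 10 lower. The median log2 ratio of the list was -1.24 (95% interval of the median -1.74 to 0.06), outside the range of -0.20 to 0.18 that held 95% of random lists of matched size and expression. H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823 and Cd74 (ENSMUSG00000024610) on chromosome 18 from 60803848 to 60812652, in mouse build GRCm38 (mm10).

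Interferon genes and costimulatory molecules lay lower in diabetic macrophages too. The interferon-gamma response list had a median log2 ratio of -0.61 (-1.26 to -0.30, random lists -0.13 to 0.15), with 11 of 20 measured members at least 1.5-fold lower. Among them were the guanylate-binding protein Gbp2 (66.2 and 26.2 CPM) and Cd274, the ligand of the inhibitory receptor PD-1 (74.0 and 48.4 CPM). The type I interferon response list stood at -0.55 (-0.90 to -0.39, random lists -0.15 to 0.15), with 10 of 21 members lower. The antiviral gene Rsad2 stood at a ratio of 0.309 (0.259 to 0.367) and Oasl2 at 0.609 (0.523 to 0.707), and Rsad2 had the opposite direction in cells called female. With finer clusters the type I list stood at -0.28 and the interferon-gamma list at -0.37, or at -0.43 and -0.53 with the unnamed groups. Costimulation and maturation genes stood at -0.61 (-0.67 to -0.13, random lists -0.20 to 0.18), with 7 of 11 lower and 1 higher, including Cd83 (ratio 0.646), Marcksl1 (0.647) and Cd86 (0.621), a ligand of CD28 on T cells. MHC class I presentation stood at -0.33 (-0.56 to -0.23, random lists -0.15 to 0.13), with 4 of 18 lower, among them H2-K1 (ratio 0.582), H2-T23 (0.537) and the peptide transporter Tap1 (0.658).

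Some lipid-associated genes lay higher in diabetic macrophages. The lipid-associated macrophage list had a median log2 ratio of 0.33 (-0.04 to 0.97, random lists -0.15 to 0.13), with 5 of 18 members at least 1.5-fold higher and 0 lower, and at 0.07 with finer clusters, or 0.34 with the unnamed groups. Fatty acid and cholesterol genes stood at -0.01 (-0.17 to 0.22), with 0 of 21 beyond 1.5-fold. Lgals3, a galectin, stood at 1270 and 2483 CPM (ratio 1.96, 1.92 to 1.99), Ctsl, a lysosomal protease, at 507.9 and 1026 CPM (2.02, 1.96 to 2.08), and the fatty acid-binding Fabp5 at 407.8 and 823.8 CPM (2.02, 1.95 to 2.09). The list of advanced glycation and S100 ligands stood at 0.42 (-0.11 to 0.68, random lists -0.20 to 0.14), with 4 of 12 higher and 2 lower, including the calcium-binding S100a6 (ratio 1.66) and S100a4 (1.60). Smaller shifts, with 0 members beyond 1.5-fold, were seen for glycolysis (median 0.23, -0.02 to 0.30, 19 members) and nuclear-encoded oxidative phosphorylation (0.19, 0.15 to 0.28, 46 members). Insulin and FOXO signalling genes stood at -0.32 (-0.42 to -0.13, random lists -0.12 to 0.12), with 2 of 28 lower, the growth factor Igf1 at a ratio of 0.416 (0.378 to 0.456) and Sesn3, a FOXO target, at 0.604 (0.450 to 0.805).

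Single genes with large macrophage differences included Cxcl13, a chemokine that attracts B cells, at 9.55 CPM in the normoglycemic and 99.03 CPM in the diabetic library (ratio 10.4, 8.62 to 12.6). Cxcl13 (ENSMUSG00000023078) lies on chromosome 5 from 95956951 to 95961068. Higher too were St3gal5, which makes the ganglioside GM3 (ratio 5.99, 4.90 to 7.37), Gpnmb, a glycoprotein of lipid-laden macrophages (5.57, 5.15 to 6.02), and Arg1, the arginine-degrading arginase (3.80, 3.63 to 3.99). So were the lysozyme gene Lyz1 (3.02, 2.88 to 3.16), the matrix protein gene Ecm1 (2.65, 2.57 to 2.74), the sodium pump subunit gene Fxyd2 (2.63, 2.53 to 2.74) and the caveolin gene Cav1 (2.44, 2.14 to 2.80). Lower were Rnase2a, an eosinophil-associated ribonuclease (ratio 0.0936, 0.0716 to 0.121), Fcrls, a scavenger receptor relative (0.316, 0.285 to 0.350), Polr2l, an RNA polymerase II subunit (0.377, 0.344 to 0.413), and Retnla, a resistin-like protein induced by interleukin 4, at 1079 and 159.4 CPM (0.148, 0.141 to 0.155). Retnla (ENSMUSG00000061100) lies on chromosome 16 from 48842551 to 48844461. After thinning each cell to 1000 UMIs, an Arg1 UMI was found in 6.67% (5.24 to 8.34) of normoglycemic and 18.0% (15.6 to 20.5) of diabetic macrophages, and in 16.6% and 29.1% without thinning. The mannose receptor gene Mrc1 was found in 64.1% (61.2 to 67.0) against 55.7% (52.6 to 58.8), and in 93.5% and 87.6% without thinning. B cells, which should lack both, gave thinned shares of 0.637% and 1.83% for Arg1 and 1.59% and 0% for Mrc1, with 0 of 164 diabetic cells allowing up to 1.83%. The median depths were 11405 and 9567 UMIs in macrophages and 4770.5 and 4469 UMIs in B cells.

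**Figure D3:**
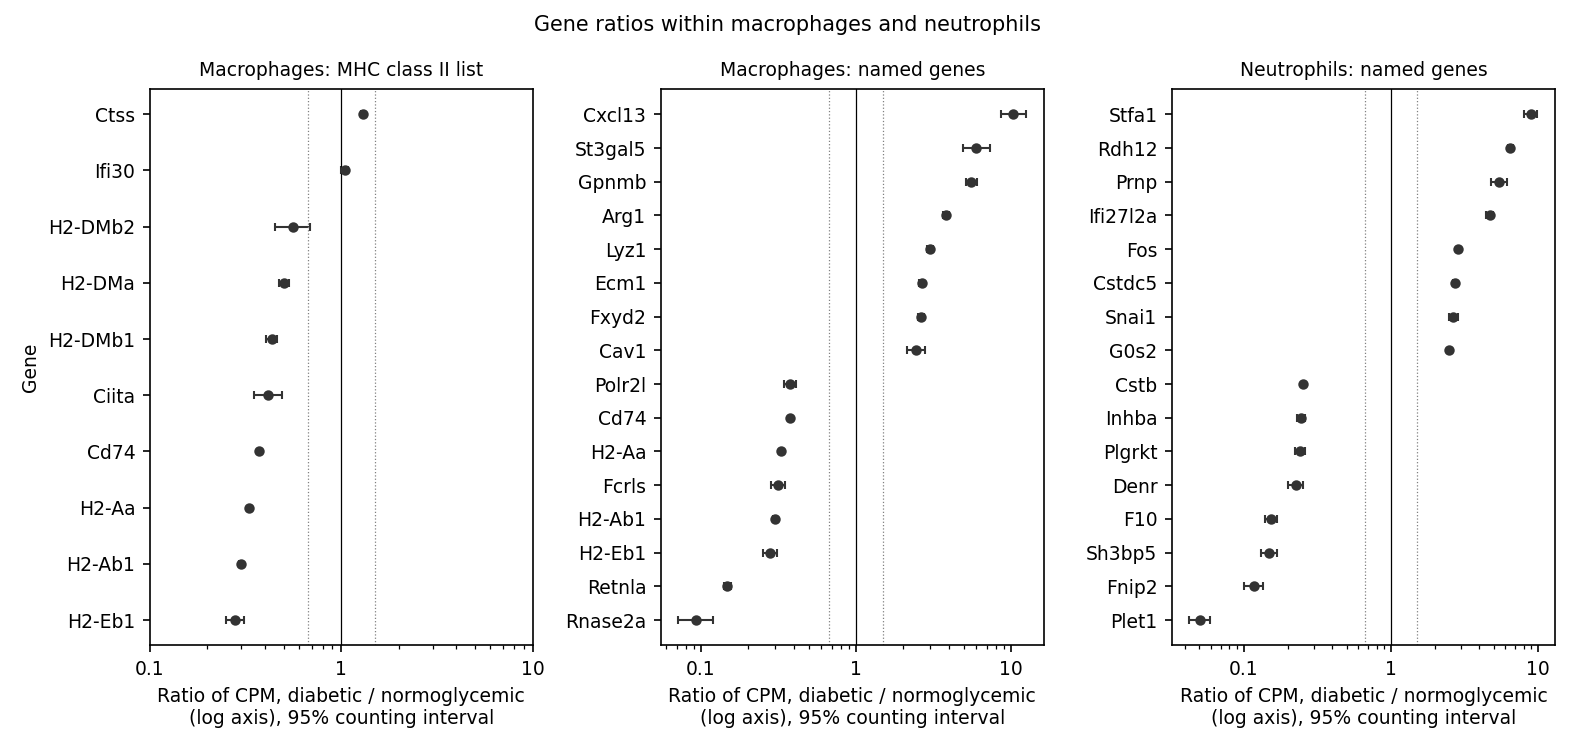
Ratio of CPM, diabetic over normoglycemic (log axis), with exact 95% counting intervals, for the MHC class II list and the named genes of macrophages and the named genes of neutrophils; each point is 1 gene in 1 library per condition. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 lay between 0.279 and 0.373, and Cxcl13 at 10.4.

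Neutrophils were compared in 5274 normoglycemic and 4834 diabetic cells, which different clusters held: mainly clusters 9 and 10 in the normoglycemic library and clusters 7 and 8 in the diabetic library. Interferon-stimulated genes were higher in diabetic neutrophils. Of the 18 measured members of the type I interferon response list, 14 were at least 1.5-fold higher and 0 lower. Ifitm3, which restricts viral entry, stood at 465.0 and 831.0 CPM (ratio 1.79, 1.74 to 1.83), the ubiquitin-like Isg15 at 349.6 and 842.9 CPM (2.41, 2.35 to 2.48) and Ifi27l2a at 77.8 and 364.6 CPM (4.69, 4.45 to 4.94). The median log2 ratio was 0.94 (0.65 to 1.26, random lists -0.26 to 0.47). The median gene of this class stood at 0.12, and scaling by the trimmed mean of M values (TMM) or by size factors shifted every log2 ratio by -0.13 or -0.19. Relative to these scalings the interferon list stood at 0.81 and 0.75. It stood at -0.01 in the 37 normoglycemic and 207 diabetic neutrophils called female. A neutrophil cluster led by interferon genes was 1.34% (1.14 to 1.58) of normoglycemic and 4.38% (3.99 to 4.79) of diabetic cells, and without it the list stood at 0.82. With the normoglycemic clusters weighted to the diabetic mix of cells, the list stood at -0.34. Within single clusters it stood at 0.872 in cluster 9, 0.569 in cluster 8 and 0.315 in cluster 7. It stood at -0.098 in cluster 5, -0.095 in cluster 10 and -0.34 in the interferon-led cluster 6. The clusters were formed on the same expression values, and cluster 8 held 140 normoglycemic and 1505 diabetic cells. Makeup of the class was therefore not separated from changes within cells.

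Granule genes and nuclear-encoded respiratory chain genes were also higher in diabetic neutrophils. The granule protein list had a median log2 ratio of 0.83 (0.07 to 1.81, random lists -0.33 to 0.43) and 0.70 with TMM, with 9 of 15 members higher and 1 lower. Among the higher ones were the protease inhibitor Slpi (3310 and 6180 CPM), the lysozyme Lyz2 (518.1 and 888.4 CPM) and Ngp (91.8 and 377.5 CPM). In cells called male, Ngp had the opposite direction and the list a median of 0.22. Nuclear-encoded oxidative phosphorylation stood at 0.77 (0.65 to 0.81, random lists -0.12 to 0.34) and 0.64 with TMM, with 36 of 44 members higher and 0 lower. Mitochondrially encoded genes went the other way, at -0.55 (-0.64 to -0.48, random lists -0.37 to 0.44), with 5 of 12 lower and 0 higher. Ribosomal protein genes stood at 0.47 (0.39 to 0.52, random lists -0.09 to 0.24), with 24 of 82 higher and 1 lower. Nuclear-encoded examples were the cytochrome oxidase subunit Cox8a (ratio 1.59) and the ATP synthase subunits Atp5l (1.75) and Atp5e (1.59). Lipid-associated genes were lower, with 7 of 12 members beyond 1.5-fold and a median of -0.66 (-1.15 to -0.05, random lists -0.33 to 0.46) or -0.79 with TMM. Among them Spp1, which encodes osteopontin, stood at 2507 and 677.8 CPM (ratio 0.270, 0.265 to 0.276), the lysosomal protease Ctsb at 784.8 and 362.5 CPM (0.462) and the tetraspanin Cd9 at 2961 and 1896 CPM (0.641). Genes of endoplasmic reticulum stress stood at -0.45 (-0.93 to -0.13, random lists -0.35 to 0.47) and -0.58 with TMM, with 4 of 14 lower and 0 higher, including the stress transcription factors Atf3 (ratio 0.578) and Atf4 (0.526) and the chaperone Dnajb9 (0.520). With the same weighting of clusters, oxidative phosphorylation stood at 0.01, granule proteins at 0.43, lipid-associated genes at -0.22 and endoplasmic reticulum stress at -0.27.

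Among single genes higher in diabetic neutrophils, Stfa1 and Cstdc5, inhibitors of cysteine proteases, had ratios of 8.90 (8.03 to 9.89) and 2.72 (2.64 to 2.80), the retinol dehydrogenase Rdh12 6.48 (6.21 to 6.76) and the prion protein gene Prnp 5.44 (4.82 to 6.16). The immediate early factor Fos had a ratio of 2.88 (2.81 to 2.94), the transcription factor Snai1 2.65 (2.47 to 2.85) and G0s2, an inhibitor of fat breakdown, 2.497 (2.48 to 2.52). Stfa1 (ENSMUSG00000071562) lies on chromosome 16 from 36276951 to 36285373. Plet1, a membrane glycoprotein gene, stood at 183.8 CPM in the normoglycemic and 9.27 CPM in the diabetic library (ratio 0.0504, 0.0429 to 0.0590). Plet1 (ENSMUSG00000032068) lies on chromosome 9 from 50494525 to 50505482. Lower too were Fnip2, a partner of folliculin (0.117, 0.101 to 0.135), Sh3bp5 (0.149, 0.131 to 0.168), and coagulation factor F10 (0.154, 0.140 to 0.169). The group further held the translation factor Denr (0.227, 0.201 to 0.255), the plasminogen receptor Plgrkt (0.241, 0.223 to 0.260), the activin subunit Inhba (0.245, 0.230 to 0.261) and the protease inhibitor Cstb (0.255, 0.249 to 0.262). In the normoglycemic library F10, Denr and Inhba stood at 185.0, 83.09 and 269.9 CPM in neutrophils. The other cells had 292.2, 110.9 and 453.7 CPM, so free RNA was not excluded as their source.

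Fewer diabetic neutrophils held a UMI of 3 immune regulators. After thinning to 1000 UMIs, the tumour necrosis factor gene Tnf was found in 48.4% (47.0 to 49.7) of normoglycemic and 23.9% (22.6 to 25.1) of diabetic cells. Il1rn, the natural antagonist of interleukin 1, was found in 86.6% (85.6 to 87.5) against 62.5% (61.1 to 63.8), and Cd274 in 30.7% (29.4 to 31.9) against 10.6% (9.76 to 11.5). Without thinning the shares were 69.8% and 41.8% for Tnf, 96.1% and 83.2% for Il1rn, and 54.9% and 23.7% for Cd274. B cells gave thinned shares of 5.73% and 3.05% for Tnf, 11.5% and 4.27% for Il1rn, and 4.14% and 4.27% for Cd274. The median depths were 3993.5 and 3414.5 UMIs in neutrophils and 4770.5 and 4469 UMIs in B cells.

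Monocytes, the blood-derived precursors of many tissue macrophages, were compared in 1236 normoglycemic and 1248 diabetic cells, held mainly by cluster 2 in the normoglycemic and cluster 3 in the diabetic library. Some type I interferon and antioxidant genes were lower in diabetic monocytes. Of 19 measured members of the type I interferon response list, 4 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.41 (-0.55 to 0.05, random lists -0.20 to 0.21). The lower ones included Slfn5 (151.9 and 100.5 CPM), Ifi209 (129.2 and 76.4 CPM) and the antiviral Oasl1 (18.1 and 8.71 CPM). The interferon-gamma response list was not lower, at 0.15 (-0.30 to 0.35, random lists -0.20 to 0.25), and its member Cxcl10 was higher (2.30, 2.08 to 2.55). The antioxidant and NRF2 target list stood at -0.33 (-0.64 to 0.22, random lists -0.20 to 0.19), with 7 of 22 lower and 1 higher, including the metal-binding Mt1 (ratio 0.603), the cystine carrier Slc7a11 (0.642) and heme oxygenase Hmox1 (0.486). Insulin and FOXO signalling stood at -0.31 (-0.40 to -0.04, random lists -0.22 to 0.15), with 6 of 23 lower, among them the insulin receptor substrate Irs2 (ratio 0.628), the receptor gene Igf1r (0.640) and the glucose-responsive Txnip (0.656). Nuclear-encoded oxidative phosphorylation stood at 0.29 (0.22 to 0.33, random lists -0.18 to 0.06), with 0 of 46 members beyond 1.5-fold. Ribosomal protein genes stood higher, at 0.54 (0.51 to 0.56, random lists -0.08 to 0.13), with 25 of 83 higher, and mitochondrially encoded genes at -0.43 (-0.51 to -0.31).

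Single genes higher in diabetic monocytes included the signalling regulator Rgs1 (ratio 2.91, 2.67 to 3.17), the chemokine Ccl24 (2.71, 2.48 to 2.97), the tubulin-binding Tppp3 (2.54, 2.34 to 2.75) and the apolipoprotein Apoc2 (2.36, 2.21 to 2.51). The histone genes Hist1h1e (10.9, 9.01 to 13.4), Hist1h4d (6.31, 5.23 to 7.65) and Hist1h1c (3.83, 3.31 to 4.44) were also higher, and the first pair was at least 1.5-fold higher in all 8 classes compared. Lower were the protein C receptor Procr (ratio 0.202, 0.180 to 0.226), the vasoconstrictor endothelin gene Edn1 (0.215, 0.179 to 0.256), AA467197 (0.287, 0.251 to 0.328), and Spata7 (0.315, 0.272 to 0.363). So were the fungal receptor Clec4n (0.338, 0.321 to 0.355), the interferon-inducible Ifi202b (0.354, 0.337 to 0.372), the adhesion protein gene Flrt3 (0.364, 0.344 to 0.384) and the metalloproteinase inhibitor Timp1 (0.378, 0.366 to 0.391). An Il1rn UMI was found in 68.9% (66.2 to 71.5) of normoglycemic and 47.0% (44.2 to 49.8) of diabetic monocytes after thinning and in 89.1% and 74.4% without it. An Arg1 UMI was found in 25.2% (22.8 to 27.8) against 35.3% (32.6 to 38.1) after thinning and in 38.8% and 46.1% without it. In B cells the thinned shares were 11.5% and 4.27% for Il1rn and 0.637% and 1.83% for Arg1, at median depths of 4770.5 and 4469 UMIs against 11097.5 and 9777.5 UMIs in monocytes. In the 61 normoglycemic and 296 diabetic monocytes called female, Ccl24, Tppp3, Procr, Edn1, AA467197, Timp1, Oasl1, Mt1, Slc7a11, Hmox1 and Il1rn had the opposite direction, and oxidative phosphorylation stood at -0.01.

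Conventional dendritic cells, which carry antigen to T cells, were compared in 988 normoglycemic and 840 diabetic cells. Cluster 0, which scored highest for type 2 dendritic cell markers, held most of the normoglycemic cells and cluster 4, which scored highest for type 1 markers, most of the diabetic cells. Cluster 0 held 660 normoglycemic and 362 diabetic cells and cluster 4 held 328 and 478. Differences were not computed within either cluster, so a shift in their mix was not separated from changes within cells. Genes of alternative activation were lower in the diabetic library, with 7 of 13 measured members at least 1.5-fold lower, 1 higher and a median log2 ratio of -0.63 (-1.10 to 0.08, random lists -0.21 to 0.17). Retnla stood at 1292 and 276.4 CPM (ratio 0.214, 0.206 to 0.222), the lectin gene Mgl2, a type 2 marker, at 893.2 and 417.3 CPM (0.467, 0.453 to 0.482) and Mrc1 at 381.5 and 246.1 CPM (0.645, 0.618 to 0.673). The anti-inflammatory and pro-resolving list stood at -0.41 (-0.79 to 0.10, random lists -0.18 to 0.16), with 7 of 18 lower and 1 higher, including Il1rn (ratio 0.578), the cytokine gene Il10 (0.527) and the receptor Axl (0.434), which clears dying cells. Fatty acid and cholesterol genes stood at -0.39 (-0.71 to -0.05, random lists -0.16 to 0.12), and at -0.04 over members of at least 50 CPM. Of 24 members 8 were lower, including the cholesterol exporter Abca1 (0.661) and Insig1 (0.504). Insulin and FOXO signalling stood at -0.30 (-0.38 to -0.02, random lists -0.15 to 0.11), with 3 of 25 lower and 1 higher, the lower ones being Klf4 (0.519), Ccr7 (0.615) and Igf1r (0.575). Endoplasmic reticulum stress genes stood at 0.21 (0.01 to 0.59, random lists -0.17 to 0.15), with 4 of 16 higher and 1 lower, including the folding factors Pdia6 (1.504), Manf (1.54) and Sdf2l1 (1.54).

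Single genes higher in diabetic conventional dendritic cells were Fxyd2 (ratio 4.11, 3.69 to 4.58), the interferon-induced membrane protein genes Ifitm6 (2.83, 2.58 to 3.10), Ifitm1 (2.55, 2.49 to 2.61) and Ifitm3 (1.82, 1.78 to 1.86). They also included the surface antigen Ly6a (2.51, 2.34 to 2.70), the histone gene Hist1h1c (2.48, 2.22 to 2.77), Tnfsf9, a costimulatory ligand (2.45, 2.37 to 2.55), and the stress-induced Ddit4 (2.30, 2.13 to 2.48). Hist1h1c had an interval wholly above 1.5-fold in 7 of the 8 classes compared. In the diabetic library Fxyd2, Ifitm6 and Ly6a stood at 105.8, 116.8 and 168.8 CPM in these cells. The other cells had 142.9, 143.6 and 196.1 CPM, so free RNA was not excluded as their source. Lower ones, besides Retnla, were the fatty acid transporter Slc27a3 (0.229, 0.191 to 0.273), Fcrls (0.253, 0.232 to 0.275), and the neurturin receptor Gfra2 (0.366, 0.316 to 0.422), followed by Mpp7 (0.381, 0.341 to 0.424), Pxdc1 (0.390, 0.340 to 0.445), the elastase Mmp12 (0.393, 0.364 to 0.423) and the semaphorin receptor Nrp2 (0.395, 0.360 to 0.433). An Mrc1 UMI was found in 28.0% (25.3 to 31.0) of normoglycemic and 18.8% (16.2 to 21.6) of diabetic cells after thinning and in 69.2% and 52.7% without it, against 1.59% and 0% of thinned B cells. The median depths were 17005.5 and 15053 UMIs against 4770.5 and 4469 UMIs in B cells. Among cells called female the opposite direction was found for Il1rn and for the endoplasmic reticulum stress list, and Il10 and Ccr7 reversed under other alternatives.

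Lymphoid cells were compared to describe the adaptive and innate-like arms of the response. Alpha-beta T or NK cells numbered 713 and 318, held mainly by cluster 21, which scored highest for regulatory T cell markers, in the normoglycemic library. In the diabetic library cluster 17, which scored highest for NK markers, held the largest part, followed by cluster 21. Cluster 21 held 415 normoglycemic and 122 diabetic cells and cluster 17 held 203 and 143. Differences were not computed within these clusters, so a shift in their mix was not separated from changes within cells. Regulatory T cell genes were lower in the diabetic library, with 11 of 17 measured members at least 1.5-fold lower, 0 higher and a median log2 ratio of -0.77 (-0.94 to -0.24, random lists -0.30 to 0.12). The costimulatory receptor Icos stood at 961.6 and 403.8 CPM (ratio 0.420, 0.388 to 0.454), the transcription factor Ikzf2 at 764.1 and 262.2 CPM (0.343, 0.311 to 0.378) and the inhibitory receptor Ctla4 at 543.8 and 305.9 CPM (0.563, 0.512 to 0.617). A UMI of Foxp3, the lineage factor of regulatory T cells, was found in 9.61% (7.54 to 12.02) against 4.10% (2.20 to 6.91) after thinning and in 25.3% and 11.3% without it. T helper 1 and cytotoxic genes stood higher, at a median of 0.36 (-0.07 to 0.74, random lists -0.30 to 0.08), with 5 of 19 higher and 2 lower. The higher ones included the chemokines Ccl5 (1651 and 4178 CPM) and Xcl1 (665.2 and 1361 CPM) and granzyme Gzmb (283.7 and 475.1 CPM). A Gzmb UMI was found in 13.4% (10.99 to 16.15) against 19.6% (15.3 to 24.4) after thinning and in 23.7% and 28.9% without it. B cells gave thinned shares of 0% and 0% for Foxp3, where 0 of 314 and 0 of 164 cells allow up to 0.955% and 1.83%, and 0.319% and 0% for Gzmb, at median depths of 4770.5 and 4469 UMIs against 5257 and 5030 UMIs.

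Other T and NK cell groups were lower in the diabetic library. Activation and inhibitory receptors stood at -0.63 (-0.83 to -0.05, random lists -0.29 to 0.08), with 11 of 20 members lower and 3 higher, including the adhesion receptor Cd44 (ratio 0.512). The type I interferon list stood at -0.43 (-0.998 to -0.23, random lists -0.32 to 0.08), with 8 of 21 lower, among them Ifi27l2a (0.468), Bst2 (0.617) and Slfn5 (0.497). MHC class II genes stood at -1.65 (-1.80 to -0.29, random lists -0.43 to 0.24), with Cd74 at 1600 and 458.5 CPM, H2-Aa at 747.9 and 239.0 CPM and H2-Ab1 at 649.5 and 194.7 CPM, but at 0.42 once cells with the highest doublet scores were removed. Single genes higher in these cells were Prelid2 (ratio 8.02, 5.35 to 12.3), Il23a, a subunit of interleukin 23 (5.08, 3.59 to 7.27), and the histone genes Hist1h1e (7.90, 6.25 to 10.1), Hist1h1c (4.16, 3.40 to 5.10) and Hist1h4d (4.03, 3.28 to 4.95). In the diabetic library Il23a stood at 56.97 CPM in these cells and at 57.63 CPM in the other cells. Free RNA was therefore not excluded as the source of Il23a. Lower were the enkephalin precursor Penk (0.186, 0.124 to 0.270), the antiviral Ifit1 (0.269, 0.177 to 0.395), the peptidase Cpm (0.271, 0.193 to 0.371), the integrin Itgav (0.287, 0.225 to 0.362) and the transcription factor Hlf (0.292, 0.212 to 0.394).

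Gamma-delta or type 17 T cells, which guard barrier tissues, numbered 340 and 190 in cluster 18 and carried more interleukin 17 transcript in the diabetic library. Il17a, which recruits neutrophils through epithelial cells and was 1 of the markers that named the class, stood at 2503 and 13040 CPM (ratio 5.21, 5.06 to 5.36), and its relative Il17f at 181.7 and 910.3 CPM (5.01, 4.49 to 5.60). Il17f (ENSMUSG00000041872) lies on chromosome 1 from 20777146 to 20790617. The epithelial growth factor Areg stood at 1557 and 4366 CPM (2.80, 2.69 to 2.92). After thinning, an Il17a UMI was found in 45.1% (39.7 to 50.6) of normoglycemic and 64.2% (56.9 to 71.0) of diabetic cells, an Il17f UMI in 7.12% (4.62 to 10.4) against 14.4% (9.74 to 20.3). An Areg UMI was found in 24.0% (19.6 to 29.0) against 45.5% (38.2 to 52.9). The unthinned shares were 64.7% and 76.8% for Il17a, 15% and 26.3% for Il17f, and 36.8% and 58.4% for Areg. In B cells the thinned shares were 0.319% and 0.610% for Il17a and 0.637% and 0% for Areg. For Il17f they were 0% and 0% (0 of 314 and 0 of 164, allowing up to 0.955% and 1.83%), at median depths of 4770.5 and 4469 UMIs against 6570.5 and 5312 UMIs. The type 17 list as a whole stood at 0.26 (-0.16 to 0.44, random lists -0.19 to 0.14), with 3 of 17 higher, Il17a, Il17f and the scavenger receptor Cd163l1 (1.54), and 0 lower. Insulin and FOXO genes stood at -0.33 (-0.81 to -0.16, random lists -0.24 to 0.10), with 9 of 26 lower, including Klf4 (ratio 0.560), Klf2 (0.568), which governs T cell trafficking, and the death-promoting Bcl2l11 (0.427). Other higher genes were Spry1 (3.76, 2.88 to 4.93), the glutathione transferase Gstp1 (3.65, 2.91 to 4.59), the linker histone H1f0 (3.24, 2.27 to 4.63) and the survival gene Bcl2a1a (2.38, 2.14 to 2.66). Lower were the T cell kinase Lck (0.0518, 0.0140 to 0.135), the cytotoxic granule gene Nkg7 (0.148, 0.0834 to 0.245), Ctla2a (0.152, 0.113 to 0.2), the CD40 ligand Cd40lg (0.164, 0.104 to 0.248) and Pxdc1 (0.297, 0.240 to 0.364), and Lck, Nkg7 and Cd40lg reversed with doublets kept or finer clusters. With finer clusters the class held 232 normoglycemic and 177 diabetic cells. In alpha-beta T or NK cells Il17f went the other way, at 50.23 and 15.49 CPM (ratio 0.3083, 0.2003 to 0.4579). A shift of type 17 cells between these classes was therefore not separated from changes within cells.

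B cells numbered 320 and 164 in cluster 11, and antibody genes were higher in the diabetic library. Of 17 measured members of the antibody secretion list, 11 were at least 1.5-fold higher and 3 lower. The light chain Igkc stood at 17170 and 122000.0 CPM (ratio 7.11, 7.03 to 7.19), the mucosal heavy chain Igha at 482.8 and 36880.0 CPM (76.4, 71.8 to 81.3) and Jchain, which joins IgA and IgM units, at 947.3 and 20280.0 CPM (21.4, 20.5 to 22.4). Igha was higher in the other 7 classes too, and the salivary genes Bpifa2 (0 and 48.94 CPM) and Dcpp1 (0.469 and 102.6 CPM) were higher in these cells, so salivary tissue or free RNA was not excluded as a source. Few cells were rich in antibody transcripts: 3 of 320 normoglycemic and 12 of 164 diabetic cells took over 20% of their UMIs from immunoglobulin genes. The list median was 1.38 (0.38 to 2.83, random lists -0.61 to -0.04), 0.33 with every cell weighted equally and -0.60 in cells called male. The median gene stood at -0.36, and TMM and size factors shifted log2 ratios by 0.33 and 0.31, which put the list at 1.71 and 1.69. Endoplasmic reticulum stress genes stood at 0.11 (-0.35 to 0.52, random lists -0.59 to -0.08) and 0.44 with TMM, but -0.51 in cells called male. Of 15 members 3 were higher and 1 lower, the higher ones being the secretory factor Xbp1 (2.61, 2.22 to 3.08), Herpud1 (2.35, 1.99 to 2.79) and Sdf2l1 (1.58, 1.27 to 1.96). Other higher genes were Serpina3f (51.6, 17.1 to 255), Prg2 (48.7, 28.7 to 89.8) and the histone genes Hist1h2ap (18.6, 13.2 to 26.7) and Hist1h2bc (9.61, 6.69 to 14.2). Hist1h2ap had an interval wholly above 1.5-fold in 7 of the 8 classes compared and Hist1h2bc in 5. Lower were Mir142hg (0.260, 0.151 to 0.423), the chemokine Ccl8 (0.273, 0.169 to 0.422), the corepressor Tle3 (0.284, 0.176 to 0.440), Bach2, which holds back plasma cell differentiation (0.298, 0.225 to 0.389), and the apolipoprotein Apoe (0.373, 0.341 to 0.406). In the normoglycemic library Ccl8 and Apoe stood at 69.4 and 1346 CPM in B cells and at 138 and 2669 CPM in the other cells. Free RNA was therefore not excluded as their source. Igkc, Prg2, Xbp1 and Sdf2l1 had the opposite direction in cells called male, and Ccl8 reversed under 4 alternatives.

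Mature dendritic cells numbered 190 and 143 in cluster 14, and interferon genes were lower in the diabetic library. Of 29 measured type I interferon genes, 25 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.19 (-1.44 to -0.79, random lists -0.30 to 0.10). Ifi27l2a stood at 1518 and 884.8 CPM (ratio 0.583, 0.551 to 0.617), Rsad2 at 866.2 and 399.8 CPM (0.462, 0.4256 to 0.5003) and Bst2, which tethers budding virus, at 597.2 and 328.3 CPM (0.550, 0.502 to 0.602). The interferon-gamma response list stood at -0.56 (-0.85 to -0.32, random lists -0.34 to 0.12), with 11 of 22 lower and 0 higher. Examples were the chemokine Cxcl9 (0.593) and the transcription factor Irf1 (0.537). Cxcl9 had the opposite direction in cells called male. The cluster also held monocyte-like cells: the monocyte chemokine Ccl2 stood at 926.6 and 80.26 CPM (0.0866, 0.0735 to 0.102), and 82 cells of the class fell into a monocyte group led by Rsad2 with finer clusters (68 normoglycemic, 14 diabetic). The mature dendritic cells then numbered 118 and 130, of which 114 and 127 came from the class, and the type I list stood at -1.14 and the interferon-gamma list at -1.08, but Rsad2 at 1.26. Ribosomal protein genes stood at 0.57 (0.53 to 0.60) in the class, with 38 of 83 higher.

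**Figure D4:**
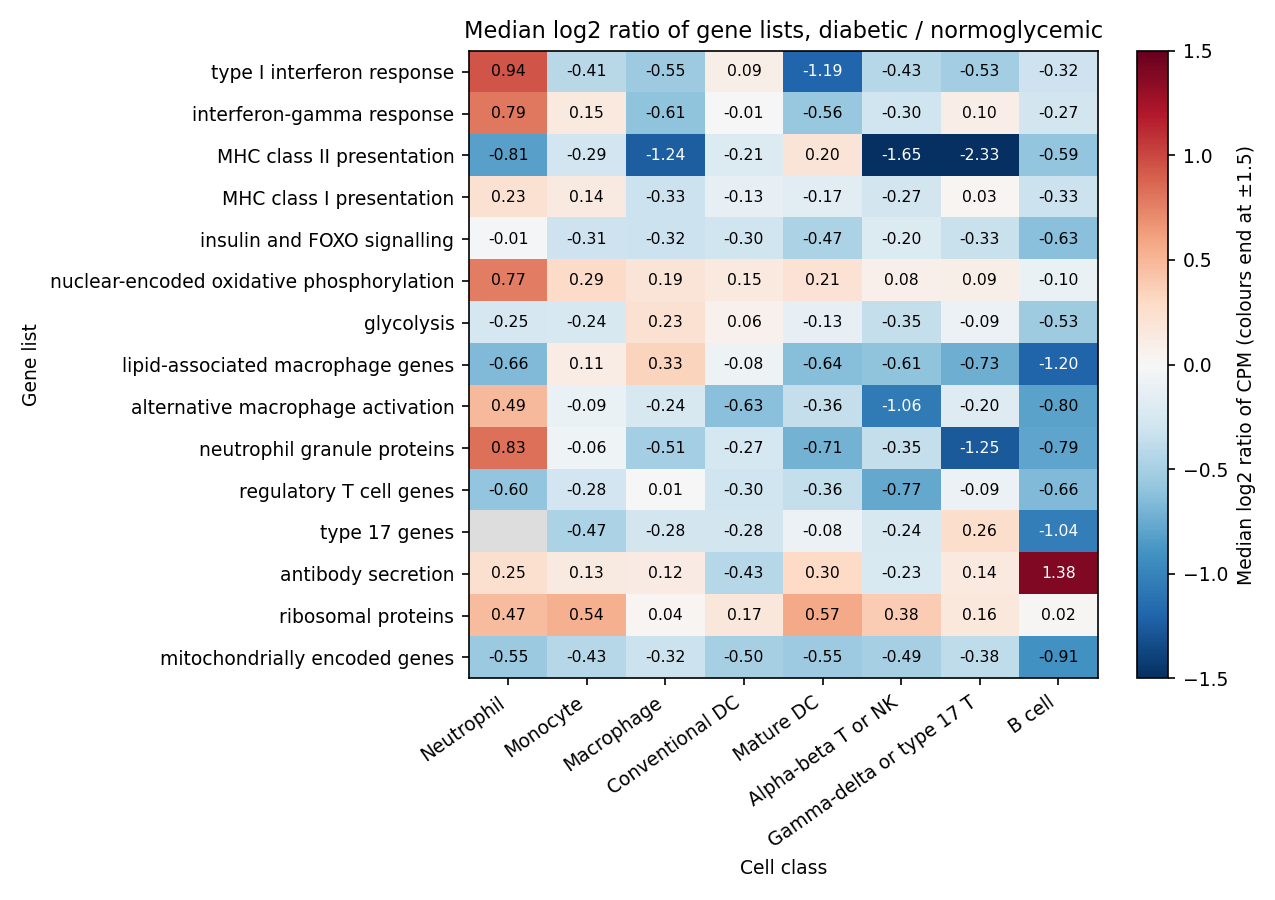
Median log2 ratio of CPM, diabetic over normoglycemic, of gene lists (vertical axis) in each cell class (horizontal axis), as colours that end at 1.5 on either side of 0, with grey for fewer than 5 measured members. The type I interferon list was above 0 in neutrophils (0.94) and below it in macrophages (-0.55) and mature dendritic cells (-1.19).

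Foxo1, the gene that the loxP sites flank, and its pathway were compared across classes. In alpha-beta T or NK cells Foxo1 stood at 107.4 and 89.6 CPM (ratio 0.834, 0.694 to 0.999) and in macrophages at 17.4 and 16.0 CPM (0.915, 0.747 to 1.12). In B cells it stood at 146.4 and 90.8 CPM (0.620, 0.496 to 0.770), beside a class median of -0.36. The insulin and FOXO list stood below 0 in all 8 classes, at -0.63 in B cells (-0.30 with TMM), -0.47 in mature dendritic cells, -0.20 in alpha-beta T or NK cells and -0.01 in neutrophils, where 4 alternatives put it above 0 (up to 0.18), besides the classes already given. It lay inside the range of random lists in neutrophils (-0.23 to 0.42) and in alpha-beta T or NK cells (-0.29 to 0.04), and outside it in the other classes.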

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

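The tests of explanations below, including those on male-called and female-called cells and on tag counts, were chosen after the results were seen, although thinning to 1000 UMIs had been fixed before as an alternative setting. Antibody-derived tags named C1 to C4 were deposited with both libraries but the labels do not say what they mark, and they were not used to assign cells. Over 100 tag counts were found for 392 of 11280 normoglycemic barcodes (3.48%, 3.14 to 3.83) and 225 of 10496 diabetic barcodes (2.14%, 1.88 to 2.44). These barcodes held 85.8% and 82.6% of all tag counts, and 386 and 225 of them had over 90% of their counts on 1 tag. The median of the other barcodes was 8 and 3 tag counts. Among tagged barcodes 253 normoglycemic and 124 diabetic ones were called male and 12 and 9 female. Leaving the tagged cells out left the type I interferon median of neutrophils at 1.0 on the log2 scale, against 0.94 with them.

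MHC class II genes were lower in diabetic macrophages, with Cd74 at 0.373 times its normoglycemic level. H2-Ab1 and H2-Eb1 had intervals wholly beyond 1.5-fold lower in 5 of the 8 classes compared, macrophages included, and H2-Aa and Cd74 in 4. In alpha-beta T or NK cells H2-Aa stood at 747.9 and 239.0 CPM, but the list there stood at 0.42 without the highest doublet scores. RNA of dendritic cells, free or in doublets, stayed open. The 8 lower MHC class II genes would need a median of 24.7% dendritic cell RNA in normoglycemic macrophages. The 7 genes used as specific to dendritic cells implied 0.888%, at most 9.34% by 1 gene. They were chosen at 5 or more times their level in macrophages of both libraries. That choice kept any implied share below 24.7%, so these genes could not decide. Strain variants within the MHC region were argued against by Cd74 and by Ciita, the master regulator of class II genes, at 0.373 and 0.416, which lie outside it, and by a median of -0.40 for H2-Aa, H2-Ab1 and H2-Eb1 in conventional dendritic cells. The sex makeup of the pools was argued against by list medians of -1.25 in male-called and -1.53 in female-called macrophages. A shift between groups of macrophages as the whole cause was argued against by a list median of -0.88 with the normoglycemic finer clusters weighted to the diabetic mix. A part for such a shift stayed open (-1.19 to -0.28 within 4 finer clusters). Differences between the mice of each pool, between 2 single libraries and in the tissue dissected stayed open as well.

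Type I interferon genes were higher in diabetic neutrophils, at a median of 0.94. With every cell thinned to 1000 UMIs the median was 0.90. CPM already divides by depth and thinning keeps each cell's expected proportions, so this could not decide on sequencing depth. Free RNA of other cells might raise these genes in the other classes too, and only 1 of the 7 other classes had a median above 0. Those classes express such genes themselves, with Ifi27l2a at 1134 and 530.5 CPM in alpha-beta T or NK cells. Their own levels could hide free RNA, so this comparison could not decide. In male-called neutrophils the median was 0.92, which argued against sex makeup, although female-called neutrophils gave -0.01 on 37 and 207 cells. More cells of the interferon-led neutrophil cluster were argued against as the whole cause by 0.82 without it. With the normoglycemic clusters weighted to the diabetic mix the median was -0.34, which a shift between groups of neutrophils would give. Within clusters 9, 8 and 7 the median was 0.872, 0.569 and 0.315, and within clusters 5, 10 and 6 it was -0.098, -0.095 and -0.34. A part for such a shift stayed open, and the weighting could not show it to be the whole cause. A response to diabetes, or to an infection of single mice in a pool, that moved cells between clusters also stayed open and untested.

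Lymphoid classes were a smaller share of the diabetic library. Dilution by cells that are not leukocytes was argued against by a difference of -6.48 points (-7.37 to -5.58) among leukocyte classes alone. A different yield of the CD11c enrichment was argued against by -9.22 points (-10.5 to -7.89) among classes outside the gate. The sex makeup of the pools was argued against by -5.23 points among male-called and -16.5 points among female-called cells. The data give shares, so fewer lymphoid cells, more neutrophils outside the gate, or tissue digestion that released cell types unequally all stayed open, and cell counts per tissue would be needed to tell them apart. Leukocytes from salivary or other tissue in the diabetic sample were not excluded either. Cells that are not leukocytes were 8.85% of the diabetic and 0.548% of the normoglycemic library.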

How the results depend on the processing

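The alternatives that removed the highest doublet scores, tagged cells, non-immune cells or the cells of one called sex, shares outside the CD11c gate, and resolution 2.0 for genes and lists were added after the results were seen. The others had been fixed before the results were seen. No paired analysis was possible because each condition had 1 library. Values below are those that reversed or, among the leading results, left the interval of the value reported, with the macrophage MHC class II list added. The cause was not tested. Share differences are in percentage points, gene values are ratios and list values are median log2 ratios. A difference is called reversed where its sign changed and its interval had excluded no difference. Shares, genes and lists are called similar where the value lay inside the interval of the value reported. Settings that left under 50 cells of a class in a library were left out here, and female-called neutrophils were used only to weigh sex makeup.

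Of the share differences in all kept cells, 65 were similar to the value reported, 19 differed from it and 6 reversed, all of mature dendritic cells. Among lymphoid cells 24 were similar, 8 differed and 0 reversed, among antigen-presenting cells 17, 13 and 2, and for neutrophils outside the gate 5, 3 and 0. Differences within counting error changed sign too: those of neutrophils, monocytes and macrophages in all kept cells, of alpha-beta T or NK cells among lymphoid cells, and of macrophages and mature dendritic cells among antigen-presenting cells. Of the gene ratios 1397 were similar, 900 differed and 39 reversed, of the list medians 764, 65 and 4, and of the regulator shares 51, 41 and 0.

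With the looser cell filter, the difference was 2.97 for neutrophils, 0.166 for mature dendritic cells, -4.26 for alpha-beta T or NK cells, -0.452 for gamma-delta or type 17 T cells and 12.6 for neutrophils outside the gate. It was -8.12 for alpha-beta T or NK and 9.68 for gamma-delta or type 17 T cells among lymphoid cells, and 0.495 for mature dendritic cells among antigen-presenting cells. With the stricter filter it was -0.207 for monocytes and -0.0175 for conventional dendritic cells, and among antigen-presenting cells -0.871 and -0.229. The stricter filter also put Ccr7 at 1.09 in conventional dendritic cells and the type I interferon list at -0.66 in monocytes and -1.58 in mature dendritic cells.

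Keeping doublets added only 2 cells, yet clusters formed differently. The difference was then 0.253 for mature dendritic cells, -4.26 for alpha-beta T or NK cells (-8.24 among lymphoid cells) and -0.404 for gamma-delta or type 17 T cells (9.31 among lymphoid cells). Among antigen-presenting cells it was 0.632 for monocytes, 2.90 for macrophages and 0.774 for mature dendritic cells. Lck stood at 1.60, Nkg7 at 8.01 and Cd40lg at 2.40 in gamma-delta or type 17 T cells, Ccl8 at 1.03 in B cells and the monocyte type I interferon list at -0.68.

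At resolution 0.5 the difference was -0.00939 for monocytes and 0.129 for mature dendritic cells, and 0.205 and 0.391 among antigen-presenting cells. At resolution 2.0 it was -2.52 for macrophages, 0.189 for mature dendritic cells, -4.29 for alpha-beta T or NK cells and -0.394 for gamma-delta or type 17 T cells, with -8.39 and 9.41 for the last pair among lymphoid cells. Among antigen-presenting cells it was -6.13 for macrophages, 0.922 for conventional and 0.962 for mature dendritic cells. Ccl8 stood at 1.03 in B cells, Lck at 1.60, Nkg7 at 7.99 and Cd40lg at 2.40 in gamma-delta or type 17 T cells, Rsad2 at 1.26 in mature dendritic cells and the monocyte type I interferon list at -0.77. The MHC class II list stood at -0.46 in macrophages, with 2 of 11 members at least 1.5-fold lower. That value counted as similar only because the interval of the reported median was wide.

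With the libraries clustered separately the difference was 9.32 for neutrophils (13.6 outside the gate), 5.05 for monocytes, -2.77 for macrophages, 0.373 for mature dendritic cells and -1.11 for type 2 innate lymphoid cells. Among lymphoid cells it was 3.64 for alpha-beta T or NK and -8.20 for type 2 innate lymphoid cells, and among antigen-presenting cells 12.1 for monocytes, -10.2 for macrophages and 0.934 for mature dendritic cells. Ccl8 stood at 1.03 in B cells and Il10 at 1.23 in conventional dendritic cells, and the type I interferon list at -0.60 in monocytes and -1.81 in mature dendritic cells.

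With the highest doublet scores removed the difference was -6.23 for neutrophils (7.57 outside the gate) and 0.261 for mature dendritic cells (0.766 among antigen-presenting cells). In alpha-beta T or NK cells the MHC class II list then stood at 0.42, Cd74 at 1.16, H2-Aa at 1.46 and H2-Ab1 at 1.02. Ccl8 stood at 1.06 in B cells, Ccr7 at 1.03 in conventional dendritic cells and the monocyte type I interferon list at -0.75. Without non-immune cells the difference was 3.24 for neutrophils, 1.99 for monocytes and 1.03 for macrophages. Thinning put Oasl1 at 1.11 in monocytes, and equal weights put the B cell antibody list at 0.33.

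Among male-called cells Prg2 stood at 0.317, Igkc at 0.768, Xbp1 at 0.575, Sdf2l1 at 0.448 and the antibody list at -0.60 in B cells, Ngp at 0.582 in neutrophils, and Cxcl9 at 1.14 and the type I interferon list at -1.97 in mature dendritic cells. Among female-called monocytes Ccl24 stood at 0.915, Tppp3 at 0.326, Procr at 2.54, Edn1 at 4.80, AA467197 at 1.61, Timp1 at 10.98 and Oasl1 at 10.1. Mt1 stood at 3.30, Slc7a11 at 2.02, Hmox1 at 1.20, Il1rn at 1.87, Il1f9 at 3.30 and Hcar2 at 3.31, with the type I interferon list at -1.12 and oxidative phosphorylation at -0.012. Female-called cells further gave 2.07 for Rsad2 in macrophages, 1.19 for Il1rn and -0.042 for endoplasmic reticulum stress in conventional dendritic cells, and -1.02 for regulatory T cell genes.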

Other observations

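The lists and genes in this part were chosen after their values were seen, and alternatives on male-called and female-called cells were added then too. Targets of NF-kB, a central switch of inflammation, had a median log2 ratio below 0 in all 8 classes. The median was -0.33 in macrophages (random lists -0.15 to 0.12), -0.30 in conventional dendritic cells (-0.14 to 0.14) and -0.29 in neutrophils (-0.25 to 0.38). It was -0.26 in monocytes (-0.23 to 0.16), -0.57 in B cells (-0.56 to -0.09, and -0.24 with TMM scaling) and -0.15 in mature dendritic cells (-0.29 to 0.21), the only class inside the range of random lists. In alpha-beta T or NK cells it was -0.315 (-0.267 to 0.062). Members at least 1.5-fold lower were 2 of 21 in conventional dendritic cells, 1 in monocytes, 4 in macrophages and 6 in alpha-beta T or NK cells. The neutrophil transcript S100a8 was also lower in other classes (3967 and 2545 CPM in monocytes, 5023 and 1667 CPM in B cells), so less free neutrophil RNA may have added to the pattern outside neutrophils, which was not tested.

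Il1rn, Il1f9, which encodes the epithelial and myeloid cytokine interleukin 36 gamma, and Hcar2, a receptor for ketone bodies and niacin, were lower in all 8 classes. In neutrophils Il1rn stood at 5103 and 2127 CPM, Il1f9 at 888.7 and 455.6 CPM and Hcar2 at 1839 and 758 CPM. The ratios over classes ran from 0.181 to 0.587 for Il1rn, from 0.0585 to 0.513 for Il1f9 and from 0.0804 to 0.415 for Hcar2. In female-called monocytes Il1rn, Il1f9 and Hcar2 reversed to 1.87, 3.30 and 3.31, and lower values in classes that express little of them may come from less free neutrophil RNA, which was not tested.

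Mitochondrially encoded genes had medians below 0 in all 8 classes, from -0.91 in B cells (-0.58 with TMM scaling) to -0.32 in macrophages. Immediate early genes, which tissue dissociation can induce, stood below 0 in 7 classes, from -0.32 in macrophages to -0.05 in alpha-beta T or NK cells, and at 0.08 in monocytes. In neutrophils 3 of 21 were higher and 7 lower. The salivary genes Bpifa2, Dcpp1, Dcpp2, Dcpp3, Wfdc12 and Wfdc18 and the antibody gene Igha were higher in the diabetic library in all 8 classes, with ratios of 135.8 for Dcpp1 and 284.7 for Bpifa2 in neutrophils and 0 normoglycemic counts of Bpifa2 in the other 7 classes. Of all cell barcodes, 32 occurred in both libraries.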
